A study of Homo sapiens with 4 samples.

How the data were processed

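Small RNA was sequenced from parental cells and spheres of HT29 and HCT15. Libraries were made from total RNA with the TruSeq Small RNA kit, per the labels' protocols. The deposited HT29 values are raw read counts per mature miRNA, and the deposited HCT15 values are RPKM, per the file headers, which name miRBase R19 as the source of the miRNA names. The genome build was hg19, per the submitters' processing notes. The aligner, trimming and treatment of reads that map to several miRNAs are not given in the sources used here.

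Listed reads totalled 5806540 and 12794274 in HT29 parental cells and spheres. The HCT15 RPKM values summed to 516401 and 612602, which behaves more like RPM than like a value per kilobase of a mature miRNA. Steps between low values put 1 read at 0.162 in HCT15 parental cells and 0.263 in spheres, giving about 3189981 and 2325417 reads. Within a tolerance of 0.02 reads, 64.7% of 408 and 62.0% of 200 low values were whole, against 13.4% and 14.2% of random values. In HCT15 parental cells the lowest step also occurred at 0.157, 0.160 and 0.164, so the value of 1 read differs slightly between miRNAs, and the inferred reads are approximate. In spheres the commonest value was 0.527, taken as 2 reads, although 4 reads would make 66.0% whole and the read total higher, and 6 miRNAs were at 1 read against 133 in parental cells, so a listed 0 there can be a dropped single read. A count of 0 allowed up to 3 reads, or 0.517, 0.234, 0.940 and 1.29 CPM in HT29 parental cells and spheres and HCT15 parental cells and spheres. Reads carry no molecular identifiers, so intervals and this floor cover counting error only.

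The HT29 files listed 1921 names and the HCT15 files 2041, of which 1882 were in all 4 files. Comparisons across lines used those 1882, since a name missing from a file is not a 0. Names were matched as written, so a miRNA named differently in the files of the lines was left out. One such case was miR-98, listed under that name for HT29 and as miR-98-5p for HCT15. The plan had taken missing names as 0, and this was changed after the names were seen. Of 2080 names, 2051 were matched by name to a hairpin in GENCODE 29 (GRCh38), which gives the positions here; no position was taken from or moved to hg19.

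Spheres were compared with parental cells across both lines with limma 3.58.1 in R 4.3.3, on log2 of the TMM-scaled CPM plus 1, with cell line as a block, for miRNAs at 10 CPM or more in at least 2 libraries. A fold change on this scale understates that of scarce miRNAs. The plan named edgeR for counts and limma for other units; since HCT15 is in RPKM, limma was the test used. Its mean-variance trend was chosen after the files were seen. The fit had 1 residual degree of freedom and a median of 2.87 prior degrees of freedom. The 2 lines are the replicates, and nothing says that a line's cultures were repeated. P-values thus measure the spread between these lines, moderated by a variance trend pooled over miRNAs. The SE of a miRNA is not the spread of its own 2 ratios. For miR-93-5p these were 0.344 in HT29 and 0.336 in HCT15, with an SE of 0.31. edgeR 4.0.16, DESeq2 1.42.0 and limma-voom were run on the HT29 counts and the rounded HCT15 read equivalents as alternatives. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

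Within a line no single miRNA was tested. The log2 ratio used TMM scaling and a prior count of 2, with an exact conditional binomial 95% interval, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The 24 miRNA lists, each member represented by its arm with the most reads, were set against 10000 random lists matched on mean expression and, with at least 3 tested members, against other miRNAs by camera with a preset correlation of 0.01 and an estimated one. Within a line, the lists left out a member whose chosen name was not in that line's files, such as miR-98 in HCT15. They cover let-7, miR-17~92 and paralogs, miR-200, pluripotency, intestinal epithelium, HOX loci, miR-34, the miR-183 cluster, colorectal tumours, hypoxia, miR-15/16, miR-232724, miR-29, miR-30, miR-181, miR-148 and miR-152, DLK1-DIO3, C19MC, stroma, blood cells, neural tissue, muscle, liver and endothelium, and entries overlapping other RNAs.

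The naming rules, lists, tests and alternatives were fixed before the data were examined, apart from the changes stated. The rules named up to 12 miRNAs per direction past the threshold across lines (there were 0) and, since fewer than 10 passed, the 10 highest and 10 lowest smaller-of-both ratios of the same sign with a mean of at least 50 CPM over the 4 libraries. They also named the 8 highest and 8 lowest ratios within a line at that minimum over its libraries, the 5 most abundant miRNAs per library, up to 4 members of each list, and the 6 miRNAs with the largest opposite ratios at that minimum whose intervals exclude 0. A further rule, for differences between the lines, was not used. The planned test between HT29 and HCT15 was not run, because the lines were deposited in different units and normalized separately, so line and processing cannot be told apart. For the same reason its alternatives were left out. No name was repeated within a file, so summing repeated names did not apply.

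The tests were tried on simulated libraries with 60 of 377 miRNAs changed, each by the same amount in both lines. Changes that differ between the lines were not simulated. At a biological coefficient of variation of 0.1, limma recovered 8 of 20 miRNAs changed 2-fold, 16 of 20 changed 4-fold and 15 of 20 changed 8-fold, with 0 false calls, edgeR recovered 19, 20 and 20 of 20 with 2 false calls, and DESeq2 13, 18 and 18 of 20 with 0. At 0.3 limma recovered 0 of 20 at each size, as did edgeR, while DESeq2 recovered 3, 13 and 17 of 20 with 1 false call. The median limma estimate for a true log2 change of 2 was 1.61 at 0.3, and the tolerance of this check was widened after it failed. Alternatives covered the scaling, filter, pseudocount, prior count, tool, cell line term and list correlation.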

Results

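MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured by small RNA sequencing in HT29 and HCT15, 2 established human colorectal adenocarcinoma cell lines. Each line was sampled as parental cells in serum-containing medium and as spheres in DMEM-F12 with N2 supplement, bFGF and EGF, which the submitters call sphere-derived cancer stem cells. The comparison asked which miRNAs differed between parental cells and spheres. Each line and culture had 1 library, giving 4 libraries in all, and no library had a replicate. Listed miRNA reads came to 5806540 in HT29 parental cells and 12794274 in HT29 spheres. The HCT15 values, deposited as RPKM, corresponded to about 3189981 and 2325417 reads in parental cells and spheres. miR-21-5p was the most abundant miRNA in every library, at 17.4% and 24.2% of reads in HT29 parental cells and spheres and 9.30% and 12.6% in those of HCT15. In HT29 it was followed by miR-192-5p, let-7a-5p and let-7f-5p in both cultures. In HCT15 it was followed by miR-10a-5p and miR-10b-5p in both cultures. Levels are in CPM, reads scaled to the total of listed miRNA reads in the library, and log2 ratios are spheres over parental cells after TMM scaling. Intervals are 95% intervals that cover counting error only.

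Across both lines, among miRNAs with a mean of at least 50 CPM over the 4 libraries, those with the highest shared ratios were miR-146a-5p, miR-1290, miR-4792, miR-210 and miR-146b-5p. miR-146a-5p, a miRNA induced by NF-kB signalling, went from 536 to 2454 CPM in HT29 (log2 ratio 2.78, interval 2.72 to 2.83) and from 2466 to 19450.3 in HCT15 (3.33, 3.30 to 3.37). miR-146b-5p, a near-identical paralog that can share reads with it, had ratios of 1.48 and 1.78. miR-210, the best-known hypoxia-induced miRNA, was at 143 CPM in HT29 parental cells and 579 in spheres, and at 58.3 and 144 in those of HCT15. No miRNA passed the test across lines, in which the 2 lines served as the replicates.

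In that test, limma with cell line as a block, 0 of 377 miRNAs had a Benjamini-Hochberg adjusted p under 0.05, and 21 had an unadjusted p under 0.05, of which 12 were higher and 9 lower in spheres. That number is close to what 377 tests would give at this threshold without any difference. edgeR's quasi-likelihood test on reads also called 0, with 21 at an unadjusted p under 0.05. The smallest adjusted p from limma was 0.471, shared by 5 miRNAs, among them miR-146a-5p (log2 fold change 3.05, SE 0.37), miR-4792 (2.62, SE 0.41), miR-1290 (3.06, SE 0.55) and miR-21-5p (0.93, SE 0.17), each higher in both lines. The fifth was miR-4449 (2.23, SE 0.41), named after its values were seen. Other settings did make calls: 2 miRNAs with DESeq2 size factors, 7 without a filter on low values, 5 with DESeq2 on reads and 3 with limma-voom on reads, all higher in spheres. miR-146a-5p and miR-1290 were among the calls in each of these 4 settings. Not every call rested on both lines: the 7 without a filter included miR-1246, with ratios of 3.99 in HT29 and 0.12 in HCT15. In simulated libraries with a biological coefficient of variation of 0.3, limma recovered 0 of 20 miRNAs changed 4-fold, against 16 of 20 at 0.1. Each simulated change was the same in both lines, whereas the ratios of these lines were weakly related (Pearson's r 0.134). These recovery rates thus may not hold for these data.

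**Figure D1:**
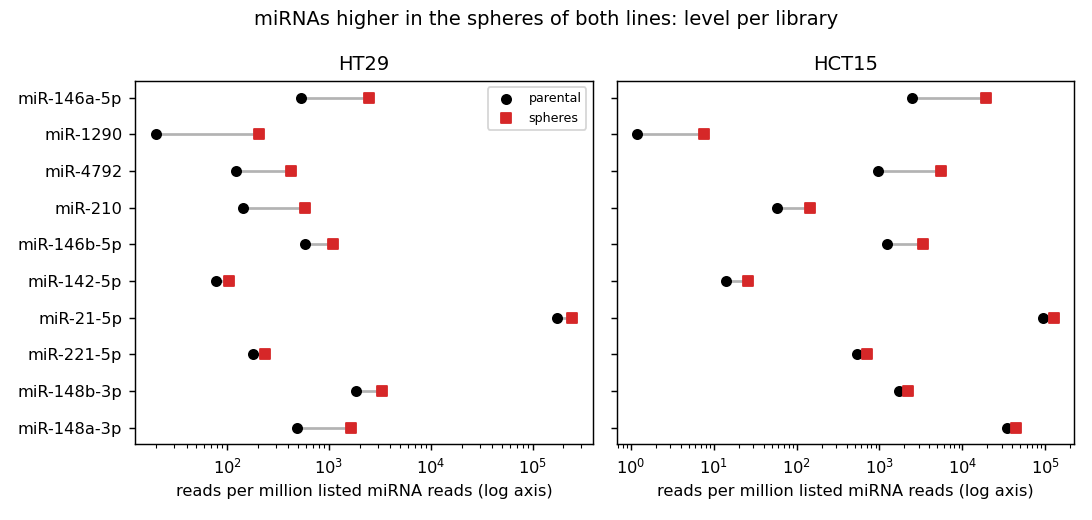
Level of the 10 named miRNAs with the highest shared ratios at a mean of at least 50 CPM, in CPM on a log axis whose range differs between the panels, with 1 library per point (circles, parental cells; squares, spheres). Each sphere library lies to the right of its parental library, as for miR-146a-5p at 536 and 2454 CPM in HT29.

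The other miRNAs named as higher in both lines were miR-142-5p, miR-21-5p, miR-221-5p, miR-148b-3p and miR-148a-3p. miR-148a-3p had a ratio of 2.35 in HT29 and 0.74 in HCT15. miR-21-5p, a miRNA abundant in many tumours, had ratios of 1.06 and 0.80. The miR-1290 ratio in HCT15 rested on 4 and 18 reads (2.40, interval 1.38 to 5.00). miR-1290 and miR-4792 are entries for which reads of other RNAs can be counted. Among miRNAs lower in both lines were miR-92a-1-5p (-2.02 and -1.03 in HT29 and HCT15), miR-25-5p (-1.58 and -1.22), miR-130b-5p (-1.73 and -0.99), miR-335-3p (-1.76 and -0.68) and miR-18a-3p (-0.66 and -1.67). In HT29, miR-25-5p rested on 44 and 20 reads and miR-92a-1-5p on 110 and 38. For the other arms miR-92a-3p, miR-25-3p, miR-130b-3p and miR-18a-5p, the HT29 ratios were -0.29, -0.76, -0.53 and -1.63. In HCT15 these other arms had -0.09, -0.30, -0.30 and 0.29. miR-589-3p and miR-590-3p were lower in both lines by less in HCT15, at -0.63 and -0.66. miR-455-3p was at 247 to 25.3 CPM in HT29 (-2.69), but in HCT15 it had 7 reads in parental cells and 0 in spheres, with an upper interval limit of 0.28. miR-590-5p had 3 and 0 reads in HCT15, with an upper limit of 2.08, and miR-371a-3p an interval of -3.33 to 0.33 in HT29. For these 3 miRNAs a shared direction was not detectable at this depth.

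Hairpin positions were taken from GENCODE 29 on GRCh38. MIR146A (chromosome 5, 160485352 to 160485450, plus strand) lies in an exon of the noncoding host MIR3142HG, and MIR146B (chromosome 10, 102436512 to 102436584, plus strand) in no annotated gene of its strand. MIR210 (chromosome 11, 568089 to 568198, minus strand) lies in an intron of MIR210HG, and MIR21 (chromosome 17, 59841266 to 59841337, plus strand) in an exonic part of VMP1. MIR148A (chromosome 7, 25949919 to 25949986, minus strand) has no host gene on its strand, and MIR1290 (chromosome 1, 18897071 to 18897148, minus strand) is intronic to ALDH4A1 and AL080251.1. MIR92A1 (chromosome 13, 91351314 to 91351391, plus strand) and MIR18A (chromosome 13, 91350751 to 91350821, plus strand) lie in exons of MIR17HG, and MIR25 (chromosome 7, 100093560 to 100093643, minus strand) in an intron of MCM7.

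In HT29, the sphere library held more miR-192-5p, miR-215 and miR-375, miRNAs of intestinal epithelium, and less miR-15b, miR-31, miR-196a-5p and miR-196b-5p. Among miRNAs with a mean of at least 50 CPM in HT29, the 8 highest ratios belonged to miR-1246 (3.99), miR-1290 (3.93), miR-1 (3.39), miR-146a-5p, miR-210 (2.60), miR-1307-5p (2.43), miR-4792 (2.38) and miR-148a-3p. miR-1, a miRNA of muscle, was at 165 CPM in parental cells and 1156 in spheres (interval 3.30 to 3.49). The 8 lowest at that level belonged to miR-31-3p (1219 to 105 CPM, -2.95, interval -3.04 to -2.87), miR-455-3p, miR-15b-5p (951 to 108 CPM, -2.56), miR-15b-3p (-2.15), miR-615-3p (-1.91), miR-135b-5p (-1.88), miR-135a-5p (-1.86) and miR-19b-3p (-1.81). MIR15B (chromosome 3, 160404588 to 160404685, plus strand) lies in an intron of SMC4, and MIR31 (chromosome 9, 21512115 to 21512185, minus strand) in an intron of MIR31HG.

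Of 226 miRNAs with a mean of at least 50 CPM in HT29, 29 were at least 2-fold higher and 44 at least 2-fold lower in spheres. This split moved with the scaling, to 11 higher and 74 lower with total counts, 19 and 54 without the 10 most abundant miRNAs, 39 and 33 with the upper quartile, and 39 and 34 with TMM on the line alone. Scaling by total counts in place of TMM shifted the log2 ratios by -0.58 in HT29 and -0.35 in HCT15, so the direction of smaller differences depended on it. With 1 library per culture the differences have no replicate check.

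In HCT15, among miRNAs with a mean of at least 50 CPM, the 8 highest ratios belonged to miR-146a-5p, miR-4792 (964 to 5522 CPM, 2.87, interval 2.81 to 2.93), miR-146b-5p (1229.8 to 3321 CPM), miR-210 (1.64, interval 1.39 to 1.92), miR-29b-3p (1.35), miR-6087 (1.26), miR-4286 (1.22) and miR-181a-5p (9842 to 17737 CPM, 1.20). The 8 lowest at that level belonged to miR-18a-3p (93.2 to 22.6 CPM, -1.67, interval -2.13 to -1.25), miR-25-5p, miR-191-3p (-1.20), miR-92a-1-5p, miR-130b-5p, miR-320c (-0.98), miR-1304-3p (-0.94) and miR-877-5p (-0.92). Of 205 miRNAs with a mean of at least 50 CPM, 9 were at least 2-fold higher and 4 at least 2-fold lower. Here too the split moved with the scaling: it was 12 and 2 with DESeq2 size factors, 5 and 21 with total counts, 16 and 1 with the upper quartile, and 6 and 9 without the 10 most abundant miRNAs. HCT15 reads were inferred from RPKM, so its intervals are approximate.

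Among the lists fixed beforehand, the miRNAs of intestinal epithelium had a median log2 ratio of 1.5 in HT29, at the 99.9th percentile of random lists matched on expression, and 3 of 4 members were at least 2-fold higher. They were miR-192-5p (92120.3 to 157860 CPM, 1.36), miR-215 (1.63) and miR-375 (2.02), while miR-194-5p was at 0.18, with a sign that changed with the scaling. Over the scalings miR-192-5p ranged from 0.78 to 1.58, so it was not 2-fold higher under each of them. The miR-148 family (miR-148a-3p, miR-148b-3p and miR-152) had a median of 2.06 in HT29, at the 99.5th percentile, with 3 of 3 members at least 2-fold higher, and 0.74 in HCT15, at the 95.0th. That count too depends on the scaling, since miR-148b-3p ranged from 0.86 to 1.67 in HT29. The pluripotency list had a median of 2.04 in HT29, at the 99.4th percentile, from miR-371a-5p, miR-372 and miR-373-3p, all at low levels of 14.5 to 62.3 CPM. The list's other members, miR-302a to miR-302d and miR-367, did not exceed 0.234 CPM in HT29 and were listed at 0 in HCT15. Lower in HT29 spheres were miR-15/16 (median -1.68, 0.675th percentile, 3 of 4 members at least 2-fold lower), the HOX-locus miRNAs (-1.31, 0.905th, 3 of 5) and miR-17~92 with its paralogs (-0.69, 1.68th, 4 of 12). Of the HOX-locus list, miR-196a-5p (-1.37) and miR-196b-5p (-1.31) were lower, whereas miR-10a-5p (-0.06) and miR-10b-5p (-0.01) were near 0 and changed sign with the scaling. In HT29, 6 of 16 lists lay outside the middle 95% of random lists. Random lists draw unrelated miRNAs, whereas several of these lists share transcripts or sequence, so the percentiles rank the lists and do not test them. In HCT15 the corresponding medians were 0.11 for the intestinal list, -0.21 for pluripotency, -0.07 for miR-15/16, 0.12 for the HOX loci and 0.29 for miR-17~92, and each changed sign with the scaling.

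In HCT15, 2 of 16 lists lay outside that range. The colorectal tumour list had a median of 0.77, at the 98.0th percentile, and 2 of 7 members were at least 2-fold higher, miR-31-5p (6012 to 10373 CPM, 1.14) and miR-135b-5p (1.91). Over the scalings miR-31-5p ranged from 0.79 to 1.40, so it was not 2-fold higher under each of them. The miR-181 family had a median of 0.62, at the 98.3th percentile, led by miR-181a-5p. In HT29 the same lists had medians of 0.25 and 0.29, which turned negative with total counts.

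**Figure D2:**
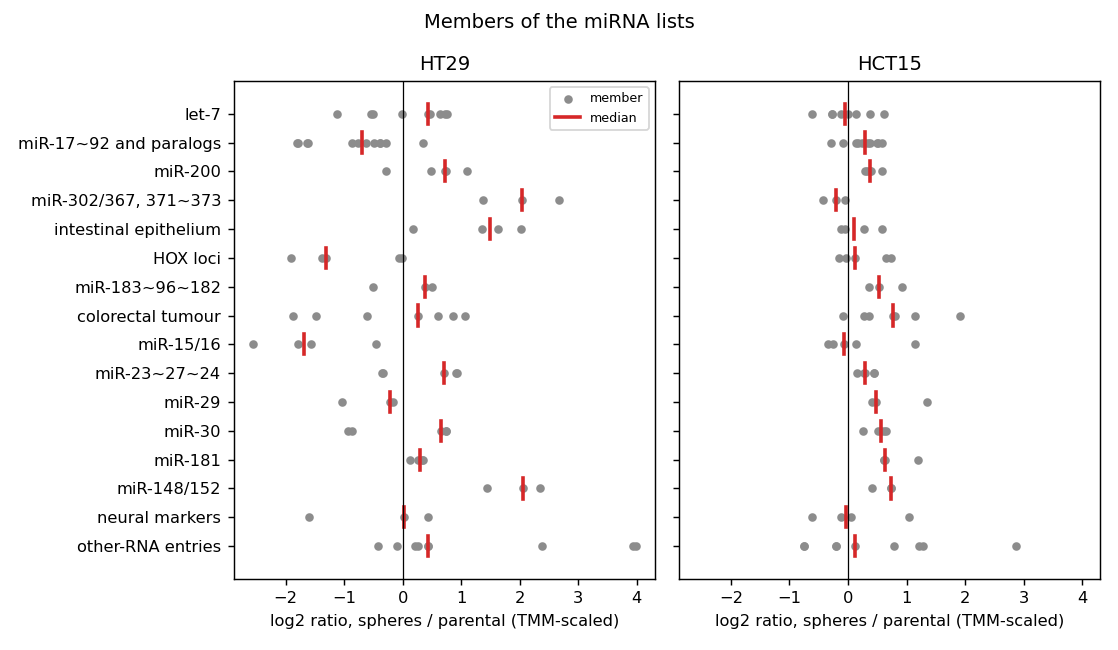
Log2 ratio of spheres over parental cells for each member of 16 miRNA lists with a mean of at least 10 CPM, in HT29 and HCT15, with 1 library per culture (dots, members; red bars, list medians). The intestinal and miR-148 lists have medians of 1.5 and 2.06 in HT29, and the miR-15/16 list of -1.68.

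Across both lines, 0 members of any list passed over all miRNAs tested. Adjusted over the list alone, limma passed miR-21-5p of the colorectal tumour list (adjusted p = 0.0437). It also passed miR-4792 and miR-1290 of the list of entries that overlap other RNAs. miR-210, the only member of the hypoxia list, had a limma p of 0.0128. For miR-516a-5p, the only tested member of the C19MC list, it was 0.0373. With 1 tested member these p-values are unadjusted, and none was adjusted over the lists. miR-516a-5p was at 0.344 and 1.80 CPM in HT29 parental cells and spheres. With total counts the smallest adjusted p over the list alone was 0.310 for the colorectal tumour list and 0.0855 for C19MC, so neither passed, whereas the hypoxia and other-RNA lists still had 1 and 2 members that passed. Of the 16 lists tested by camera with a preset correlation of 0.01, 2 passed, both up: the miR-148 family (median 1.23, 3 members, adjusted p = 0.0236) and the other-RNA list (median 0.61, 9 members, adjusted p = 0.0236). Neither passed with an estimated correlation (adjusted p = 0.669 for both), which rests on 1 residual degree of freedom. The miR-200 and intestinal lists each had an adjusted p of 0.0663 with the preset correlation.

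The remaining families stayed within the middle 95% of random lists in both lines. Medians in HT29 and HCT15 were 0.43 and -0.06 for let-7, 0.72 and 0.38 for miR-200, 0.39 and 0.53 for the miR-183 cluster, 0.71 and 0.29 for miR-232724, -0.21 and 0.48 for miR-29, and 0.65 and 0.56 for miR-30. The let-7 median covered 9 members in HT29 and 8 in HCT15. Left out in HCT15 was miR-98, listed there as miR-98-5p with a ratio of -0.13. The sign changed with the scaling for let-7 in both lines, for the miR-183 cluster and miR-29 in HT29 and for miR-232724 in HCT15. The entries that overlap other RNAs had medians of 0.43 and 0.12, and the neural markers of 0.02 and -0.03, each with a sign that changed. miR-34a-5p had ratios of -0.51 and -0.05, the second with a sign that changed. Markers of other cell types were mostly scarce. Of the blood-cell miRNAs, miR-142-3p was at 381 and 366.8 CPM in HT29 parental cells and spheres and miR-486-5p at 42.9 to 34.8 in HCT15. Of the stromal miRNAs, miR-143-3p did not exceed 6.10 CPM and miR-145-5p was at 0.172 CPM or listed at 0. Of the neural list, miR-128 had ratios of -1.60 and -0.62, and of the liver and endothelium list miR-126-5p had 0.03 and 0.31, near 0 with a sign that changed. miR-1 of the muscle list was listed at 0 in both HCT15 libraries, and its HT29 partner on the list, miR-133a, was at 0.689 to 2.74 CPM. Of the DLK1-DIO3 list, miR-379-5p was at 28.8 to 21.3 CPM in HT29 and listed at 0 in HCT15.

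The ratios of the 2 lines were weakly related. Over the tested miRNAs, without 14 that had no reads in one of the lines, Pearson's r was 0.134 and Spearman's rho 0.115, across miRNAs, which are not independent replicates. The same sign was found for 54.8%, against 49.99% expected from the share of each sign in each line. These 14 were left out after their values were seen; over all 377 the same sign was found for 52.8%, against 48.1% expected, with r at 0.131. At least 2-fold higher in both lines were 7 miRNAs, where independent lists would share 3.01, and at least 2-fold lower in both were 5, where independent lists would share 6.22. These counts depended on the settings: with total counts they were 5 and 26, where independent lists would share 0.752 and 24, and with a prior count of 10 they were 7 and 1. Those higher in both were miR-146a-5p, miR-146b-5p, miR-210, miR-1290, miR-4792, miR-142-5p and miR-4449, and those lower were miR-25-5p, miR-92a-1-5p, miR-1303, miR-455-3p and miR-590-5p, of which miR-4449 and miR-1303 lie outside the naming rules and were chosen after their values were seen. The ratios of miR-455-3p and miR-590-5p in HCT15, with 0 reads in spheres, depend on the prior count.

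**Figure D3:**
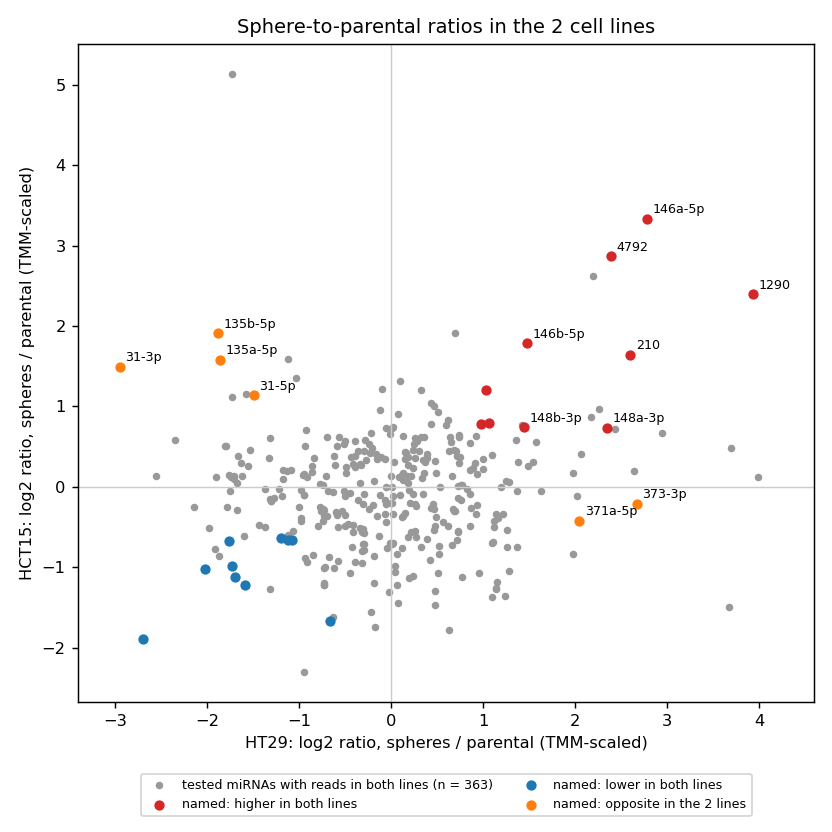
Log2 ratio of spheres over parental cells in HT29 (x axis) against HCT15 (y axis) for tested miRNAs with reads in both lines, 1 dot each, with named miRNAs in colour. miR-146a-5p lies at 2.78 and 3.33, whereas miR-31-3p lies at -2.95 and 1.49.

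The lines also differed in which miRNAs were abundant, although their files were normalized separately and no test was made between them. miR-371a-5p, of a cluster expressed in embryonic stem cells, was at 63271 CPM in HCT15 parental cells and 20.5 in HT29 parental cells. The corresponding levels were 34874 and 14.5 for miR-373-3p, and 27392 and 22.7 for miR-372. miR-192-5p was at 2582 CPM in HCT15 and 92120.3 in HT29. In HCT15 spheres, miR-371a-5p and miR-373-3p had ratios of -0.42 and -0.21, the second of which changed sign with the scaling. MIR371A (chromosome 19, 53787675 to 53787741, plus strand) and MIR373 (chromosome 19, 53788705 to 53788773, plus strand) are neighbours on chromosome 19, in no annotated gene of their strand.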

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

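The 6 results here were picked out because the ratio of spheres over parental cells went one way in HT29 and the other way in HCT15, with each counting interval excluding 0. With 1 library per culture the difference between the lines was not tested, and the files of the lines were normalized separately.

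miR-31-3p had a log2 ratio of -2.95 in HT29 and 1.49 in HCT15, a difference of -4.44, the second from 22 and 38 reads. miR-31-5p, from the other arm of the hairpin, had -1.49 and 1.14, a difference of -2.63. miR-135b-5p had -1.88 and 1.91, a difference of -3.79, and miR-135a-5p had -1.86 and 1.58, a difference of -3.44. These 2 paralogs are close in sequence and can share reads. All 4 kept their signs in both lines under the scalings tried.

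miR-371a-5p had a ratio of 2.04 in HT29 and -0.42 in HCT15, a difference of 2.46. miR-373-3p had 2.67 and -0.21, a difference of 2.88, with a range over scalings of -0.56 to 0.05 in HCT15, so its opposite direction there depends on the scaling. In HT29 both were scarce, at 20.5 and 14.5 CPM in parental cells.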

How the results depend on the processing

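The edgeR test, limma without a trend and the agreement of the lines over all tested miRNAs were added after the data were seen; the other alternatives were planned. The count of 0 miRNAs across lines became 2 with DESeq2 size factors, 7 with no filter on low values (of 1234 tested), 5 with DESeq2 on reads and 3 with limma-voom on reads, and was 0 in the other settings run; the cause was not tested. HT29 counts at least 2-fold higher and lower became 11 and 74 with total counts, and 19 were higher without the 10 most abundant miRNAs. HCT15 counts became 5 higher and 21 lower with total counts, 16 higher and 1 lower with the upper quartile, 2 lower with DESeq2 size factors and 9 lower without the 10 most abundant miRNAs. Scaling shifts all ratios of a line together. The share of miRNAs with the same sign in both lines became 65.0% with total counts, against 60.2% expected there. With an estimated correlation, 0 lists passed. Among named miRNAs and list medians, 466 values kept their side or stayed within their interval or spread, 14 passed the threshold under an alternative and 123 moved beyond their interval or spread, 44 of them with total counts. Of 32 list medians within a line, 12 changed sign with total counts or summed arms. Others changed sign only with another scaling, such as miR-29 in HT29, at -0.79 to 0.015 over the scalings. Left out of a fit, each line leaves 1 library per culture and so a value with no test. Cell line as a block pairs the libraries of a line, and without it 0 miRNAs passed. The test between the lines and its alternatives, and summing repeated names, were not run. In HCT15 spheres a 0 can be a dropped single read, so ratios of miRNAs with few reads are the least certain.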

Other observations

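The test of hairpin GC content was chosen before its result was seen, and the others were chosen after.

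Next to the miR-371a, miR-372 and miR-373-3p hairpins on chromosome 19, miRNAs of C19MC, a cluster active mainly in placenta, were detected in HCT15. miR-516a-5p was at 64.8 to 100.2 CPM (log2 ratio 0.97, interval 0.70 to 1.26), miR-512-3p at 6.90 to 19.4 (1.73, 1.07 to 2.65), miR-516b-5p at 3.76 to 15.1 (2.13, 1.37 to 3.43) and miR-519a-3p at 3.81 to 6.31 (0.94, -0.06 to 2.36). Of the 10 members of the list, 4 had an interval above 0 in HCT15, 0 had one below 0, and the other 6, at no more than 6.31 CPM, had an interval that included 0 or too few reads. These 4 include miR-525-5p, listed at 0 in parental cells and at 1.70 CPM in spheres, near the floor of 1.29 CPM there. In HT29 none of the C19MC miRNAs on the list exceeded 1.80 CPM. MIR512-1 (chromosome 19, 53666679 to 53666762, plus strand) and MIR516A2 (chromosome 19, 53761133 to 53761222, plus strand) lie upstream of MIR371A. miR-205-5p, chosen after its values were seen and below the minimum level for naming, had the highest HCT15 ratio of all miRNAs tested, 5.13 from 1.88 to 73.1 CPM, while in HT29 it went from 38.2 to 7.58 CPM (-1.73).

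The 44 miRNAs at least 2-fold lower in HT29 spheres were weighed against 2 technical explanations. After the linear trend on hairpin GC content was removed, their median log2 ratio was -1.55, against -1.58 before. The trend over 223 miRNAs was weak (Pearson's r 0.119), so a linear effect of hairpin GC is not the whole cause. Since the 44 were picked for low ratios, removing a weak trend could hardly move their median. Their median hairpin GC was 47.4%, against 52.2% for the others, so a part played by GC stays open. The mature strand's own GC was not used. Over the scalings tried, 33 to 74 miRNAs were at least 2-fold lower, so the size of the set depends on the scaling. The other arms of the same hairpins had a median of -0.49, against 0.24 for other miRNAs (difference -0.7308, bootstrap interval -1.35 to -0.24). Part of this difference was built in, since 8 of these 28 arms were in the set themselves while the comparison miRNAs lay outside it. The other 20 arms had a median of -0.15, against 0.06 for 103 partner arms of miRNAs that were not lower. These values do not exclude an effect of the mature strand's sequence in library preparation. That explanation, scaling and a response to sphere culture stay open.

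For miR-146a-5p, blood cells in the spheres were a candidate source, since it is abundant in immune cells. After TMM scaling the 6 blood-cell miRNAs and miR-142-5p together were higher by 189 CPM in HT29, 7.75% of the 2436 CPM for miR-146a-5p, and by 18.6 against 21139.9 CPM in HCT15, both under a limit of 10% set after the values were seen, which argues against that source as the whole cause. miR-142-5p, from a hairpin of blood cells, did move with miR-146a-5p (1.03 in HT29 and 1.20 in HCT15). Its other arm miR-142-3p, more abundant in HT29, had 0.53 there and 0.00 in HCT15. HT29 parental cells already held miR-142-3p at 381 CPM, against 366.8 in spheres. Both lines are established colorectal lines grown in culture, so blood cells are an unlikely source. The miR-146a-5p ratio exceeded that of miR-146b-5p in both lines, by at least 1.191 between the limits of their intervals. That argues against a fixed share of miR-146b-5p reads as the whole cause. The reverse, miR-146a-5p reads counted as miR-146b-5p, was not tested. Over the scalings tried, the lowest miR-146a-5p ratio in either line was 2.20. Chance variation between single libraries and a response to sphere culture stay open.

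miR-1246, miR-1290 and miR-4792 may reflect fragments of other RNAs, since other entries of that kind overlap tRNA, rRNA or snRNA. Those other entries had medians of 0.235 in HT29 (6 measured) and -0.207 in HCT15 (7 measured, bootstrap upper limit 1.22), so a general excess of such fragments was not seen in HT29 but stays open in HCT15. miR-1246 itself was higher in HT29 (3.99) and near 0 in HCT15 (0.12, with a sign that changed with the scaling). A source specific to these 3 entries, and a biological difference, were not tested.

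One hypothesis was that both arms of a hairpin share its change. Across hairpins, which are not independent replicates, Pearson's r between the arms' ratios was 0.3382 over 110 hairpins in HT29 (Spearman's rho 0.283, one-sided permutation p = 0.00017) and 0.538 over 74 in HCT15 (0.358, p = 2e-05). Adjusted by the Benjamini-Hochberg method over the 6 permutation tests of the 3 hypotheses, these were 0.00051 and 0.00012. Without the 2 hairpins farthest from the median, r was 0.261 and 0.347. Part of the difference may thus lie at the level of the hairpin or its transcript. Since the hypothesis was written after the data were seen, these p-values are not an independent test of it. An effect of abundance on both arms was not tested.

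A second was that hairpins within 10 kb of each other move together. Each hairpin stood in its cluster with a single arm, and the arms used could differ in kind. In HCT15 the MIR17HG cluster combined miR-17-5p (0.38), miR-19a-3p (0.50) and miR-20a-5p (0.57) with miR-18a-3p (-1.67) and miR-92a-1-5p (-1.03). An effect of this choice of arm on the differences was not tested. The mean absolute difference of ratios within clusters was 0.9246 in HT29 (18 clusters, one-sided permutation p = 0.187, adjusted 0.225) and 0.514 in HCT15 (21 clusters, p = 0.581 and adjusted 0.581), so no such relation was detected. The first criterion, a difference above the random level in both lines, would have counted this against the hypothesis; the one used, set after the result, also asks that the bootstrap interval (0.75 to 1.11 in HT29, 0.281 to 0.785 in HCT15) exclude the 5th percentile of random assignments (0.835 and 0.417), which it does not, and leaves it open.

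Another came from the minor arms among the miRNAs lower in both lines. Within hairpins whose arms differ at least 5-fold, the minor arm's ratio lay below the major arm's by a median of -0.24 in HT29 (46 of 75 hairpins, two-sided sign-flip permutation p of the mean = 0.0223, adjusted 0.0334) and -0.29 in HCT15 (30 of 42, p = 0.00098, adjusted 0.00196). Since the hypothesis was drawn from these same libraries, these p-values are not an independent test of it. Against major arms of the same abundance, however, the medians were -0.06 in HT29 (bootstrap interval -0.61 to 0.27) and 0.1113 in HCT15 (-0.18 to 0.43), so a property of minor arms could not be separated from low abundance.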
